A study of Macaca nemestrina with 12 samples.

How the data were processed

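MicroRNAs (miRNAs) were measured by quantitative real-time PCR in plasma of 6 pigtail macaques (Macaca nemestrina), each sampled before inoculation with simian immunodeficiency virus (SIV) and at 10 days post inoculation (10 dpi), which gave 12 samples. At necropsy 3 animals had severe encephalitis and 3 had none, per the labels. Of the 6 animals 5 were male and 1, replicate 1 without encephalitis, was female, so that sex could not be tested. Per the labels' protocols, total RNA was extracted from plasma after addition of a synthetic plant miRNA (ath-miR159a, the spike-in), reverse-transcribed with pooled primers, pre-amplified for 12 cycles and loaded on 2 TaqMan low-density array cards, called A and B, for each sample. The deposited values are threshold cycles (Ct), one for each of 768 wells per sample, and a lower Ct stands for more RNA. Of these wells 754 hold miRNA assays, 377 on each card, and the others hold the spike-in and the control RNAs U6, RNU44 and RNU48. U6 has 4 wells on each card. The instrument software, threshold and baseline settings are not given in the sources used here. Nor is any card lot, run or order, so that these could not be checked against the time points. A difference of that kind could not be told apart from infection. This limits every comparison between time points, including that of features detected at a single time point. The deposited values carried no scaling to the spike-in. Undetected wells were given as 40 on card A (2541 wells at 40) and as text on card B (3552 of all 9216 wells).

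Each Ct was turned into a level on the log2 scale, which assumes a doubling in each cycle. The spike-in Ct of the same sample and card was subtracted from the feature's Ct, the mean spike-in Ct of that card was added back, and the sign was turned so that a higher level stands for more RNA. A well counted as detected at a Ct below 35. Levels that were not detected, or that lay below a common floor, were set to that floor, which was the highest of the 12 samples' levels at Ct 35 (-33.72 on card A and -33.51 on card B). A change of a feature with all samples of a time point at the floor is a lower bound. Features detected in at least 5 of the 6 samples of a time point were tested between time points (218 features). For the comparisons that involve the outcome groups, features detected in all 3 samples of a group were added, which made 226. Of the 754 miRNA features, 135 were detected in all 12 samples and 414 in none. Names are those of the assays, which were designed mostly for human sequences, and no genome coordinates are given because no table used here pairs the assays with macaque positions.

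Comparisons between time points were fitted with limma for all animals, and within each outcome in one fit of all samples, with the animal as a fixed block. The difference of the changes between outcomes was the interaction contrast of that fit. Comparisons between outcomes at one time point used limma with the 4 group means and the animal as a random block (consensus correlation 0.159). All limma p-values were adjusted by Benjamini-Hochberg over the features tested, with a threshold of 0.05, and errors of log2 changes are standard errors from the fit. Samples of a time point are separate animals. The labels give the animal of each sample, and both samples of an animal are paired by it; their deviations from the group means correlated at 0.223 to 0.482 across features in the 6 animals. Whole-sample measures and control RNAs were compared with an exact two-sided sign-flip permutation test of the 6 within-animal changes, whose smallest possible p is 0.0313. Exact permutation of 3 against 3 animals cannot give a p below 0.1.

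Before the data were examined, 16 miRNA lists were fixed from general knowledge of cell or tissue of origin, virus and interferon literature, or genomic cluster. Lists with 3 or more tested features (14 between time points) were tested with camera, which compares a list with the other features (preset correlation 0.01, and again with an estimated correlation), and with fry, which asks whether a list moves one way. The interferon-beta list and the chromosome 19 placental cluster each had 1 tested feature between time points. Named miRNAs were chosen by a rule fixed at the same time. Between time points in all animals it took the 15 largest rises and the 15 largest falls past the threshold with the same sign in at least 5 of 6 animals. For other comparisons it took up to 10 in each direction, or, where none passed, the 5 with the smallest p. It added 15 fixed miRNAs and up to 4 members of each tested list with the smallest p. Of the fixed names, miR-124 was detected in no sample and let-7a in 2 samples before infection and 0 at 10 dpi, so neither was tested.

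The alternatives tried were scaling to the mean of features detected in every sample, quantile normalization, raw Ct, control RNAs or one spike-in value per sample, other detection limits and filters, undetected wells as missing, other limma settings, fits without the block, and fits without each animal. The endogenous scaling used only control RNAs detected in every sample, which were U6 on card A and U6 with RNU48 on card B. Fits of the 4 animals necropsied at 43 to 45 days, and of each card alone, were added after seeing the data. On simulated levels of 218 features of which 50 were changed, the fit for time points in all animals recovered 15.9% of changes of 1 on the log2 scale, 58.8% of changes of 2 and 82.5% of changes of 3, with 5.61% false among the calls. For the difference between outcomes it recovered 0.294%, 1.18% and 4.06% of changes of 1, 2 and 3. Analyses were run in R 4.3.3 with limma 3.58.1.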

Results

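Plasma miRNA was profiled in 6 pigtail macaques before SIV inoculation and at 10 dpi, in the acute phase of infection. The animals fell into 2 groups of 3 by the encephalitis found at necropsy, severe or none. The design thus asks how circulating miRNA changed from before inoculation to acute infection. It also asks whether levels before or early in infection differed by later outcome. All 6 animals were inoculated, so a change with time or repeated sampling could not be told apart from infection. Between 210 and 263 of the 754 miRNA features were detected in a sample, 144 to 178 on card A and 66 to 85 on card B. Repeated U6 wells of one sample and card had a pooled SD of 0.182 cycles on card A and 0.151 cycles on card B. No pair of samples shared an identical measured Ct, and the closest pair differed by a median of 0.514 cycles.

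The number of detected miRNAs was 238 ± 16.7 (SD, n = 6) before infection and 226 ± 11.3 (SD, n = 6) at 10 dpi, lower in 5 of 6 animals (exact sign-flip p = 0.0625). The mean level of the 135 features detected in all samples, relative to the spike-in, changed by -0.80 ± 0.74 (SD, n = 6) on the log2 scale and was lower in 5 of 6 animals (exact sign-flip p = 0.0625). It changed by -1.02 on card A alone and by -0.22 on card B alone (exact sign-flip p = 0.438 for card B). Neither difference passed the threshold. RNU48, a small nucleolar RNA of cell nuclei, was lower at 10 dpi in 6 of 6 animals, by -6.84 ± 2.24 (SD, n = 6) on card A and -7.09 ± 1.90 (SD, n = 6) on card B relative to the spike-in. Each had an exact sign-flip p of 0.0313, the smallest the design allows, and 0.0781 after adjustment over the 10 control measures, so none passed the adjusted threshold. U6, a small nuclear RNA, changed by -1.90 ± 2.09 (SD, n = 6) on card A relative to the spike-in and was lower in 5 of 6 animals (exact sign-flip p = 0.0938, adjusted p = 0.179). The raw spike-in level changed by 0.35 ± 0.71 (SD, n = 6) on card A (exact sign-flip p = 0.313, adjusted p = 0.313). It rose most in severe animal 3, by 1.65 on card A and 1.20 on card B. The mean level of that animal relative to the spike-in changed by -1.83, so its falls depend in large part on its spike-in wells. RNU48 was lower both in the 4 animals necropsied at 43 to 45 days (-7.77 on card A) and in the 2 necropsied at 83 and 84 days (-4.96).

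Plasma miRNAs fell more often than they rose between the time points, relative to the spike-in. Of 218 features, 114 passed the limma threshold at 10 dpi against before infection, 27 higher and 87 lower. The largest rise was that of miR-1233, 191-fold (log2 change 7.58 ± 0.56, SE, 6 animals, adjusted p = 1.52e-07), which was near the detection floor before infection. It was at the floor in severe animal 3 and in animal 1 without encephalitis, so the size of its rise is partly set by the floor. The largest falls were those of miR-210, an miRNA induced by low oxygen (-8.22 ± 0.89, adjusted p = 8.61e-06), and miR-103 (-6.29 ± 0.59, adjusted p = 2.11e-06). Both were detected in 6 of 6 samples before infection and in 1 of 6 at 10 dpi, so that their changes are set by the floor. The median change of all tested features was -0.82, and it was -0.30 with the global mean, -0.21 with quantile normalization and 0.92 with the control RNAs. The calls were 44 higher and 59 lower with the global mean, 49 and 62 with quantile normalization, and 52 and 4 with the control RNAs. That last scaling used U6 alone on card A and U6 with RNU48 on card B. Relative to the spike-in, U6 itself changed by -1.90 on card A and RNU48 by -7.09 on card B.

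Other large rises included 2 features that match fragments of lysine transfer RNA, miR-1274B (3.73 ± 0.48, adjusted p = 5.28e-05) and miR-1274A (3.27 ± 0.48, adjusted p = 0.000152), each higher in 6 of 6 animals. Large rises were also found for miR-190b (3.57), miR-34a* (3.55), miR-215 (3.33), miR-660 (3.25), miR-132 (3.09), miR-34a (2.19, or 1.23 and not past the threshold without severe replicate 1), which is induced by p53, miR-192 (2.17), miR-511 (2.11), miR-1290 (1.92), miR-375 (1.92) and miR-146a (1.92). miR-1303 was detected in 0 of 6 samples before infection and in 6 of 6 at 10 dpi, a rise of at least 5.36-fold. After miR-210 and miR-103, the largest falls were those of miR-221 (-4.71), miR-18a (-4.64), let-7g (-4.06), miR-374b (-3.77), miR-652 (-3.72), miR-15b (-3.72), miR-454 (-3.57), miR-409-3p (-3.44), let-7d (-3.39), miR-144* (-3.26), miR-432 (-3.20), miR-191 (-3.19) and miR-744 (-3.18). With the control RNAs, miR-409-3p (0.90) and miR-144* (1.00) had the opposite sign.

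**Figure D1:**
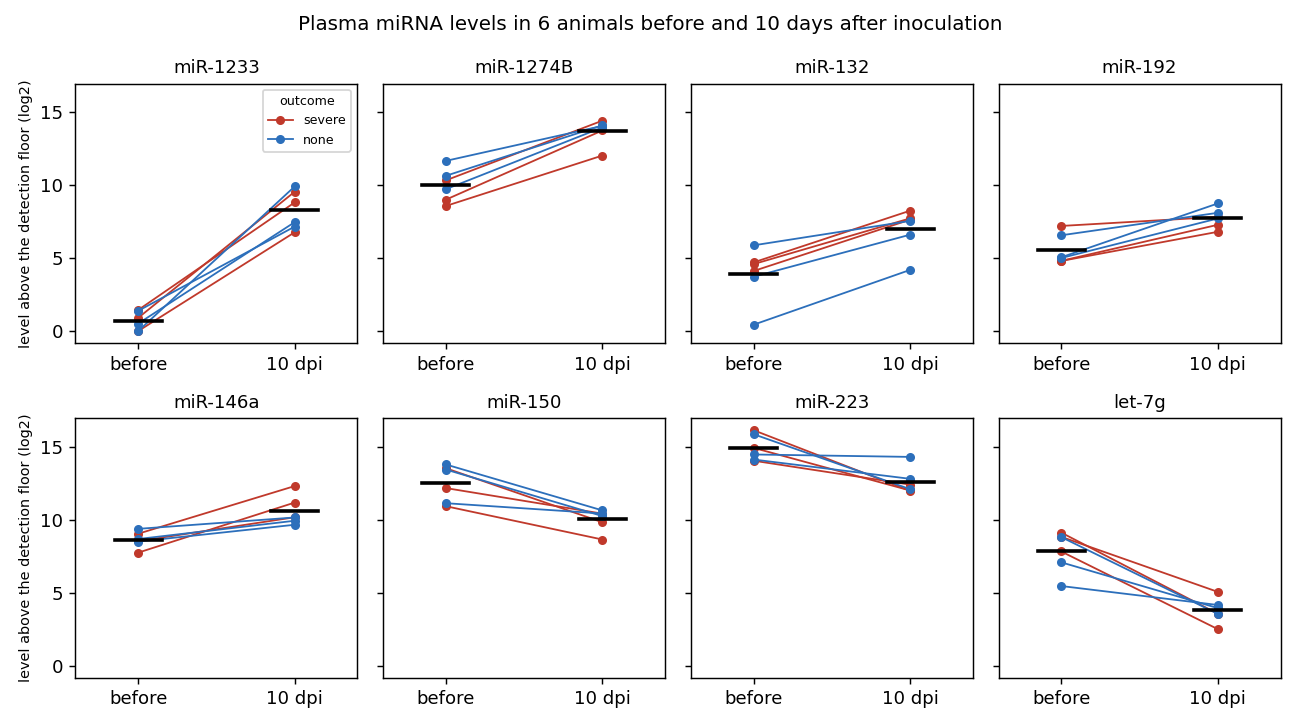
Level above the detection floor on the log2 scale (vertical axis) of 8 miRNAs before infection and at 10 dpi (horizontal axis), one line per animal, red for severe encephalitis and blue for none, with black bars at the mean of 6 animals. All 6 animals had higher miR-1233, miR-1274B, miR-132, miR-192 and miR-146a and lower miR-150 and let-7g at 10 dpi, relative to the spike-in.

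Of the 4 blood-cell lists, the erythrocyte list had the most falls. All 6 of its tested members fell over the 6 animals together (6 also when adjusted over the list alone), namely miR-451 (-2.36 ± 0.53, adjusted p = 0.00213), miR-144* (-3.26), miR-144 (-3.01), miR-486-5p (-2.44), miR-16 (-1.66) and miR-92a (-1.36). Animal 2 without encephalitis stood apart, with a mean change of the list of 0.51 and higher miR-16, miR-92a, miR-486-5p and miR-144 at 10 dpi. In that animal the median change of all tested features was also above 0 (0.25), as was the change of the mean level (0.31). Both were below 0 in every other animal, so its deviation was not confined to the erythrocyte list. The list changed by -2.98 ± 0.22 (SD, n = 3) in severe animals and by -1.72 ± 2.03 (SD, n = 3) in the others. Of 7 tested myeloid miRNAs 4 fell, including miR-223 (-2.33 ± 0.57, adjusted p = 0.0041), miR-142-3p (-2.59), miR-142-5p (-2.18) and miR-27a (-1.39, or -0.89 and not past the threshold without severe replicate 3), and 5 fell when adjusted over the list alone. Of 6 lymphocyte miRNAs 3 fell (3 adjusted over the list alone), namely miR-155 (-2.97 ± 0.55, adjusted p = 0.000607), miR-181a (-2.69) and miR-150 (-2.46), while miR-29c was at -0.65 (adjusted p = 0.301). Of 7 platelet miRNAs 3 fell, miR-191 (-3.19), miR-223 and miR-126 (-1.21), and miR-21 rose (1.67 ± 0.50, adjusted p = 0.012), with the same counts adjusted over the list alone. Camera called none of these 4 lists against the other features (adjusted p = 0.0832 for erythrocyte, 0.191 for myeloid, 0.308 for lymphocyte and 0.753 for platelet). Without none replicate 2 it called the erythrocyte list at the preset correlation (camera adjusted p = 0.0277). In all animals the erythrocyte list had a camera adjusted p of 0.698 with an estimated correlation. Fry, which asks for movement in one direction, gave adjusted p = 0.0272 for erythrocyte, 0.0273 for myeloid and lymphocyte and 0.0923 for platelet. It does not compare a list with the other features. The median of all tested features was -0.82, and fry called 8 of the 14 lists, so these values are not particular to blood cells. RNU48 was lower in 6 of 6 animals, as given above, including the animal whose erythrocyte list was not. With the control RNAs none of the 4 lists had a fall past the threshold, and 0 erythrocyte, 1 myeloid, 1 lymphocyte and 2 platelet members rose. There the erythrocyte, platelet and lymphocyte medians turned to 0.24, 1.01 and 0.34, and the myeloid median went from -1.39 to -0.04. With the global mean and with quantile normalization 4 erythrocyte members fell, and the platelet median was above 0 with quantile normalization (0.24).

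Members of 2 sets of genomic clusters and of the let-7 family fell. Of 17 tested members of the imprinted chromosome 14q32 cluster 14 fell and 0 rose (14 adjusted over the list alone, camera adjusted p = 0.0189), including miR-432, miR-409-3p, miR-487b (-2.82) and miR-376c (-2.48). Of 11 members of the miR-17 family clusters, which promote cell growth, 10 fell (11 adjusted over the list alone, camera adjusted p = 0.0243). Those with the smallest limma p were miR-18a, miR-106b (-2.28), miR-106a (-2.13) and miR-17 (-2.05). Of 5 let-7 family members 4 fell (4 adjusted over the list alone, camera adjusted p = 0.0832, fry adjusted p = 0.0128), namely let-7g, let-7d, let-7e (-3.12) and let-7b (-2.17). With an estimated correlation the adjusted p was 0.698 for each of these 3 lists. Medians stayed below 0 under every scaling tried, at -0.65 for chromosome 14q32, -0.05 for the miR-17 clusters and -1.22 for let-7 with the control RNAs, where 1, 0 and 0 members fell past the threshold. With the global mean 10 of 17, 5 of 11 and 4 of 5 members fell. The camera call of the miR-17 clusters was lost with the global mean (adjusted p = 0.0691), without none replicate 1 (0.0934), by a narrow margin without severe replicate 1, and in the 4 animals necropsied at 43 to 45 days (0.282), a fit chosen after seeing the data. That of chromosome 14q32 was lost at Ct below 32 (adjusted p = 0.132).

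Epithelial miRNAs rose, and more liver miRNAs rose than fell. Of 4 tested epithelial miRNAs 3 rose (3 adjusted over the list alone), miR-375 (1.92 ± 0.47, adjusted p = 0.00387), miR-429 (1.73) and miR-141 (1.71), while miR-203 was at 0.53 (adjusted p = 0.532). Before infection miR-429 and miR-141 lay near the floor of -33.72, with means in severe animals of -33.18 and -32.85 and in the others of -33.17 and -32.40. The sizes of their rises are thus partly set by the floor, and miR-429 changed by 0 in animal 1 without encephalitis. The list had a camera adjusted p of 0.0189 (adjusted p = 0.385 with an estimated correlation), and the call was lost at Ct below 32 (adjusted p = 0.0937). Of 4 liver miRNAs 2 rose, miR-192 (2.17 ± 0.51, adjusted p = 0.00298) and miR-885-5p (1.44), and miR-194 fell (-2.66 ± 0.83, adjusted p = 0.0156), with 3 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.0832). The fall of miR-194 did not pass with the global mean, quantile normalization or the control RNAs, where the list had 3, 3 and 2 rises and 0 falls. miR-122, the most abundant hepatocyte miRNA, was at 1.26 ± 0.59 (adjusted p = 0.0853). It was at 0.75 without none replicate 1 and passed at 2.28 with the global mean (adjusted p = 0.0215). The liver list changed by -0.52 ± 0.78 (SD, n = 3) in severe animals and by 1.63 ± 0.23 (SD, n = 3) in the others (exact permutation p = 0.1, the smallest possible). The negative mean in severe animals came from miR-194, which changed by -5.4, -3.1 and -6.5 there. In the same animals miR-192 and miR-885-5p each rose in all 3, and miR-122 changed by -0.2, 0.1 and 0.7. None of the 4 muscle and heart miRNAs passed, over all features or over the list alone, with miR-1 at 0.98 (adjusted p = 0.154), miR-133a at 0.92, miR-206 at 0.70 and miR-133b at 0.67. The camera adjusted p of the list was 0.0832, or 0.698 with an estimated correlation. At the preset correlation it was 0.0314 without severe replicate 1. Under other scalings 2 rose with the global mean, 2 with quantile normalization, 1 with raw Ct and 1 with the control RNAs, and the list median of 0.81 became 1.82, 2.03, 1.19 and 2.65.

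Relative to the spike-in, inflammation-induced miRNAs moved both ways. Of 8 tested, miR-132 (3.09), miR-146a (1.92 ± 0.52, adjusted p = 0.00674), which dampens innate immune signalling, and miR-21 rose, and 3 fell, among them miR-155 and miR-9 (-2.46), with the same counts adjusted over the list alone (camera adjusted p = 0.204). The list had 4 rises and 1 fall with the global mean and with quantile normalization, and 4 and 0 with the control RNAs, with medians of 1.04, 1.19 and 1.68. Of 8 miRNAs published as targeting HIV 5 fell and 0 rose (6 adjusted over the list alone, camera adjusted p = 0.191, fry adjusted p = 0.0157), led by miR-28-5p (-3.11), miR-150, miR-223 and miR-17. With the global mean 4 of them fell and 1 rose, with quantile normalization 3 fell and 2 rose, and with the control RNAs 0 fell and 1 rose, at list medians of -0.98, -0.37 and -0.10 against -2.00. Of 9 brain miRNAs 4 fell, including miR-9, miR-128 (-2.24) and miR-134 (-1.92, or -1.27 and not past the threshold without severe replicate 3), and 1 rose, miR-132 (4 and 1 adjusted over the list alone, camera adjusted p = 0.966), and the list median of -1.10 turned to 0.48 with the control RNAs, where 2 rose and 0 fell. With the global mean and with quantile normalization 1 brain miRNA rose and 2 fell. Of 10 endothelial and vessel wall miRNAs 2 fell, miR-221 and miR-126, and 1 rose, miR-99a (1.56), while miR-145 was at -0.74 (adjusted p = 0.312). Over that list alone 1 fell and 0 rose (camera adjusted p = 0.569). The list had 3 rises and 1 fall with the global mean, 3 and 2 with quantile normalization and 2 and 0 with the control RNAs, and its median of -0.29 turned to 0.68, 0.86 and 1.59. Of the other fixed names, miR-125b was at 0.59 (adjusted p = 0.367) and miR-29a at -0.28 (adjusted p = 0.65).

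**Figure D2:**
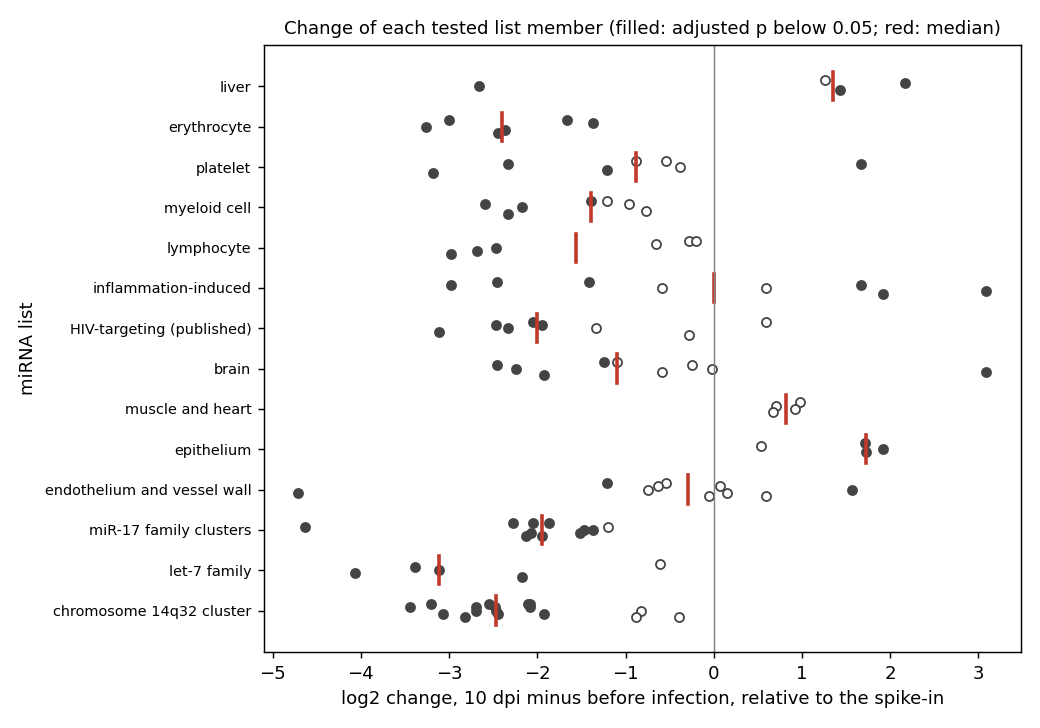
Log2 change at 10 dpi against before infection relative to the spike-in (horizontal axis) of each tested member of 14 miRNA lists (vertical axis), filled where the limma adjusted p was below 0.05, with a red line at the list median. The erythrocyte median was at -2.40 and the epithelial one at 1.72, and the erythrocyte median was at 0.24 with the control RNAs.

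In animals that later had severe encephalitis, 94 of 226 features passed, 18 higher and 76 lower. The largest rises were miR-1233 (7.60 ± 0.82, SE, 3 animals, limma adjusted p = 1.65e-05), miR-505 (4.75), miR-34a* (4.32), miR-1274B (4.10), miR-190b (3.92), miR-34a (3.70), miR-215 (3.63), miR-660 (3.53), miR-132 (3.40) and miR-1274A (3.10). The largest falls were miR-210 (-9.74), miR-103 (-7.24), miR-221 (-5.58), miR-374b (-5.31 ± 0.79, adjusted p = 0.000367), miR-194 (-4.99), let-7g (-4.89), miR-15b (-4.89), miR-18a (-4.80), miR-425 (-4.41) and miR-539 (-4.37). In all 3 severe animals miR-505 was at the floor before infection, and miR-210, miR-103 and miR-539 were at 10 dpi. The sizes of these 4 changes are therefore lower bounds. Without severe replicate 3, miR-425 was at -1.49 and miR-221 at -3.35, and without severe replicate 1 miR-34a was at 2.07, none of them past the threshold. Without severe replicate 3 the calls numbered 35, 17 higher and 18 lower, and scaling to the control RNAs gave 27 higher and 5 lower. Severe replicate 3 also had the largest rise of the raw spike-in level, as given above. The split was 42 and 59 with the global mean, 41 and 43 with quantile normalization and 31 and 62 with raw Ct.

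In animals without encephalitis, 15 of 226 features passed, 8 higher and 7 lower. The rises were miR-1233 (7.55 ± 0.82, SE, 3 animals, limma adjusted p = 3.10e-05), miR-1274A (3.44), miR-1274B (3.37), miR-190b (3.23), miR-660 (2.97), miR-34a* (2.78), miR-132 (2.77) and miR-192 (2.65). The falls were miR-210 (-6.70), miR-103 (-5.34), miR-18a (-4.47), let-7g (-3.23), miR-454 (-2.98), let-7e (-2.78) and miR-28-5p (-2.73). Of these 15, 7 rises and 7 falls were also called in the severe animals, where independent lists of those sizes share 0.637 and 2.35 features. Both changes came from the same fit with a shared spread for each feature, so the lists were not independent and that reference may overstate the agreement. Across the 226 features the changes of both outcomes had a Pearson r of 0.86, and 194 had the same sign, although features are not independent replicates. The count was 8 without the replicate block, and it ranged from 2 to 30 when single animals were left out, with 2 calls without severe replicate 3 and 4 without none replicate 3. The split of 8 and 7 moved widely, to 12 higher and 7 lower with the global mean, 10 and 6 with quantile normalization, 8 and 12 with raw Ct, 9 and 0 with the control RNAs, 9 and 21 with one spike-in value per sample and 10 and 22 with trend and robust eBayes.

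Whether the change differed between the outcomes was tested directly. By limma 0 of 226 features passed, and 13 had an unadjusted p under 0.05. The smallest p-values belonged to miR-194 (severe minus none -4.66 ± 1.17, adjusted p = 0.273), miR-134 (-3.46), miR-489 (-2.91), miR-374b (-3.09) and miR-486-3p (-3.04), the last 4 with adjusted p = 0.699. At 10 dpi miR-486-3p was at the floor in all samples. Its value here is therefore the difference before infection, given below, with the sign turned. By list, camera called the chromosome 14q32 cluster, with a median difference of -1.60 over 17 members (adjusted p = 0.00249), of which 0 passed singly, over all features or over the list alone. Its adjusted p was 0.928 with an estimated correlation and 0.793 by fry. The cluster's mean change was -3.07 ± 1.63 (SD, n = 3) in severe animals and -1.42 ± 1.37 (SD, n = 3) in the others (exact permutation p = 0.2, where 0.1 is the smallest possible). The mean of the cluster in severe animals minus that in the others was -2.05 in the 4 animals necropsied at 43 to 45 days and -0.87 in the other 2. The call was lost without none replicate 1, the 1 female among the 6 animals, necropsied at 84 days, which left 0 lists called. Before infection the mean level of each of the 17 members was higher in severe animals than in the others, as for miR-411 (-29.07 against -30.86). The difference in change was therefore in part a difference before infection. At 10 dpi miR-432, miR-539 and miR-889 were at the floor in all 3 severe animals. The liver list had a median difference of -1.52 (camera adjusted p = 0.056, or 0.928 with an estimated correlation), and it passed in 5 of the alternatives tried and not in the other 5.

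Levels before infection were compared to ask whether they differed by later outcome. By limma 0 of 226 features passed, and 13 had an unadjusted p under 0.05. The smallest p-values were those of miR-486-3p (severe minus none 3.04 ± 0.86, adjusted p = 0.335), miR-10b* (-2.26), miR-424* (2.12), miR-139-3p (-4.15), each with the same adjusted p, and miR-194 (2.59, adjusted p = 0.431). With the global mean miR-424* passed (2.80 ± 0.52, limma adjusted p = 0.0357).

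At 10 dpi, 0 of 226 features passed by limma between the outcomes, and 18 had an unadjusted p under 0.05. The smallest p-values were those of miR-885-5p, a liver miRNA (severe minus none -2.34 ± 0.64, adjusted p = 0.314), miR-489 (-2.93), miR-193b (-2.10), miR-374b (-2.83) and miR-362-3p (2.70, adjusted p = 0.354). On simulated changes the fit of the difference in change recovered few effects of the sizes tried, so that a count of 0 there does not show equal changes.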

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

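All explanations in this part were tested after the results were seen. Among 82 sets of 6 within-animal changes, 7 held 1 animal far from the other 5, and chance alone marks about 1 set in 20. In animal 2 without encephalitis the change lay apart for miR-16 (0.38), miR-92a (0.95), miR-486-5p (0.47), miR-17 (0.029) and miR-144* (-0.44), which were all between -1.55 and -4.48 in the other animals. Of these, miR-16, miR-92a, miR-486-5p and miR-144* belong to the erythrocyte list. The median change of all tested features was 0.25 in that animal, against -0.34 to -1.90 in the others, so part of the deviation went with the whole sample. In severe animal 3 miR-142-5p changed by -4.80, and in animal 1 without encephalitis, the 1 female, miR-210 changed by -1.69. The chromosome 14q32 cluster was called by camera at the preset correlation for a difference in change between the outcomes, with a median of -1.60. It was not called with an estimated correlation (camera adjusted p = 0.928), by fry (adjusted p = 0.793) or without none replicate 1. Its tested members were each higher on average in severe animals before infection, as given above.

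The fall of blood-cell miRNAs and of RNU48 at 10 dpi was weighed first. A shift of the whole sample, from RNA yield or the spike-in, would leave no change with the global mean if it were the whole cause. The 25 tested blood-cell features changed by -1.57 with the spike-in and by -0.72 ± 0.27 (SD, n = 6) with the global mean, lower in 6 of 6 animals, so that the larger part of the fall went with the scaling and a part did not. With the global mean the median of all tested features was -0.30, and camera called none of the 4 lists, with the platelet list on the upper side (adjusted p = 0.946). Red cell lysis alone before infection would leave RNU48, which mature red cells lack, but RNU48 changed by -4.49 more than the erythrocyte list on average, in 6 of 6 animals. That argues only against lysis as the sole cause of both falls. It cannot decide whether lysis contributed to the erythrocyte fall, since RNU48 may have fallen for a separate reason. U6, also a nuclear RNA, changed by -1.90 on card A relative to the spike-in and was higher in 1 animal. Less RNA of blood cells in the plasma at 10 dpi, from residual cells before infection or fewer circulating cells during it, was not tested and stays open. Lists of other origin fell as far, with medians of -2.47 for chromosome 14q32 and -3.12 for let-7, and cell counts were not analysed here.

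The second pattern was the loss of miR-210 and miR-103. Before infection their Ct ran from 23.0 to 25.4 and from 25.9 to 29.0, and at 10 dpi 10 of 12 wells were not detected. Random failure of single wells was argued against, since 0.82% of the 366 wells of 61 other features with as low a Ct were not detected at 10 dpi. A first test, against the largest fall among the 135 features detected in all samples (let-7g, -4.06), was set aside after its result was seen, because that choice leaves out features that became undetected. Card lot, run and order are not given in the sources used here, so a difference between runs could not be checked. No other technical explanation was tested, and a change with infection stays open, untested.

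The calls between time points in all animals were compared with the 32 ways of exchanging the time labels within animals. Only 1 of them, the real one, gave 114 calls, and the highest other gave 54, with the labels of animal 2 without encephalitis exchanged. A share of 1 in 32 is the smallest that these patterns can give, so the test argues against chance but does not exclude it. Within an outcome 4 patterns exist, too few for a share under 0.05; 1 of them gave the 94 calls of the severe animals and 1 the 15 calls of the others, and the highest other gave 0 in both. For the comparisons of outcomes, 10 divisions of the animals are too few as well. All 10 gave at least the real count of 0, and the highest other was 0 for the difference in change, 3 before infection and 1 at 10 dpi.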

How the results depend on the processing

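The fits of the 4 animals, of single cards, and of RNU48 without single animals were chosen after seeing the data. For all animals, the 114 calls between time points became 56 with the control RNAs. Card A alone gave 89 calls among 152 features, 18 higher and 71 lower. Card B alone gave 23 among 66, 9 higher and 14 lower, so the excess of falls lay mostly on card A. Of the 114, 84 remained in the same direction with the global mean and 26 with the control RNAs, where 28 had the opposite sign. The 94 calls of severe animals became 32 with the control RNAs, 51 with features detected in at least 1 sample and 35 to 95 without single animals. The 15 calls of the animals without encephalitis became 9 with the control RNAs, 30 with one spike-in value per sample, 30 at Ct below 32, 34 with undetected wells missing, 8 with Ct 35 put in before normalization, 35 with features detected in all 12 samples, 0 with features detected in at least 1 sample, 32 with trend and robust eBayes, 8 with no replicate block and 2 to 30 without single animals. The paired and unpaired fits differed by over 1.5 times in no other count of features, and the lists called for the difference in change went from 1 to 2 with no replicate block. All animals gave 83 to 116 calls without single animals and 97 with the 4 animals.

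For the difference in change, 1 feature passed with undetected wells missing (miR-144, -6.07) and 0 to 1 without single animals (miR-194 without severe replicate 2, -5.60). Before infection, 1 passed with the global mean and 1 with quantile normalization (miR-424* in both) and 0 to 1 without single animals (miR-486-3p without none replicate 3). At 10 dpi 0 passed without any single animal. The detected number changed by -14.2 at Ct below 38 (exact sign-flip p = 0.0313) and by -15.8 to -9.6 without single animals. The mean level changed by -1.02 to -0.59 and RNU48 by -7.45 to -6.38 without single animals, where 5 pairs cannot give an exact p below 0.0625. Lists called between time points went from 3 to 0 with an estimated correlation, 1 at Ct below 32 and 2 to 4 without single animals. For the difference in change 1 list became 0 with an estimated correlation, 2 with no replicate block, 3 at Ct below 32 and 0 to 4 without single animals.

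With the control RNAs the sign turned for miR-409-3p (0.90), miR-144* (1.00), miR-16 (0.23), miR-126 (0.69), miR-29a (1.62), miR-92a (0.53), miR-144 (0.25), miR-27a (0.41), miR-29c (1.24) and miR-145 (1.26). With quantile normalization it turned for miR-126 (0.24), miR-29a (0.89), miR-92a (0.030), miR-29c (0.44) and miR-145 (0.32), with the global mean for miR-29a (0.74), miR-29c (0.37) and miR-145 (0.28), and with raw Ct for miR-29a (0.072). Of 2224 alternative values of 120 named results, 1928 kept direction and side of the threshold, 260 lost the threshold, 17 gained it and 19 turned. Except where stated, the cause was not tested. Features near the floor are limited by the detection Ct.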

Other observations

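The explanations in this part were tested after the results were seen. Several features were nearly confined to one time point among the 12 samples. miR-1303 and miR-1267 were detected in 0 of 6 samples before infection and in 6 of 6 at 10 dpi, and miR-200b, an epithelial miRNA, in 0 and 4. miR-18a*, miR-24-2* and miR-191* were detected in 5 samples before infection and in 0 at 10 dpi, and miR-106b* and miR-590-3P in 4 and 0. These were named after their values were seen, and miR-1267 did not pass between time points (1.18 ± 0.53, limma adjusted p = 0.073).

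The rise of miR-1274A and miR-1274B, which match lysine transfer RNA, was set against miR-720 and miR-1260, also regarded as transfer RNA fragments. The first pair rose by 3.50 on average and the second by 1.35, a difference of 2.15 ± 0.97 (SD, n = 6) that was above 0 in 6 of 6 animals (exact sign-flip p = 0.0313, the smallest possible). An equal rise of these fragments was thus not found. The first pair was taken up because both were among the largest rises in these same data. That choice favours a difference above 0, so the p-value is not independent support. The spike-in well of card B did not account for it, since miR-1274B changed by 3.95 with the global mean of card B. Lysine transfer RNA is the primer that lentiviruses carry in their particles, and virus in the plasma may therefore be one source. That hypothesis was not tested, since virus load was not analysed here.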
